A study of Mus musculus with 4 samples.

How the data were processed

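RNA of bone-marrow-derived macrophages from BALB/c mice was hybridised to Affymetrix arrays in 4 states (untreated, given LPS alone, given LPS with zVAD, and given LPS with both zVAD and Nec-1), with 1 array for each, per the labels' protocols. The deposited values are gene-level signals on a log2 scale, made with Affymetrix Expression Console, per the submitters' processing notes. The log2 scale was read from the values themselves, which run from about 3 to below 15 with medians between 6.41 and 6.52 on every array. The software version, the background correction, the summarisation and the normalization between arrays are not given in the sources used here, and neither are treatment times. An unknown normalization matters because a shift or a level-dependent trend between arrays moves every ratio, so 3 further scalings of the deposited values were tried. Scanner files and detection calls of single probes were not used here. Samples were grouped by their titles.

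The table held 35556 gene-level entries, called probes here. Gene symbols came from the platform annotation that accompanies the table, under which 21789 probes had 1 symbol, 1621 had several and 12146 had none; probes with several or no symbol were not named. Of the probes with 1 symbol, 21698 carried a gene identifier found in the RefSeq gene table of GRCm38.p6, which changed 0 symbols and was otherwise used for older names of list members. No genome build is given in the sources used here, and no coordinates are reported. Probes with 1 symbol gave 19938 genes, of which 999 had more than 1 probe; each such gene was represented by its probe with the highest mean over the 4 arrays. A gene entered the counts if its highest signal on the 4 arrays was at or above the median of all values (log2 6.47), which kept 12203 genes and left out 7735.

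Every comparison was a difference of log2 signals between single arrays (log2 ratio), and a gene counted as higher or lower at a ratio of 2-fold or more. With 1 array per condition no test was made, and the threshold is a rule of size. Comparisons were LPS with control, LPS/zVAD with LPS, LPS/zVAD/Nec-1 with LPS/zVAD, and LPS/zVAD/Nec-1 with LPS. The return of zVAD differences with Nec-1 was measured as the share of genes at or past the midpoint of the LPS and LPS/zVAD log2 signals, with Wilson 95% intervals that cover counting of genes alone. Because neighbouring comparisons share an array, 200 sets of arrays were simulated with and without the observed zVAD differences. Their error was taken from the spread of LPS/zVAD/Nec-1 against LPS by signal level, an upper value for those 2 arrays because real differences add to that spread. It says nothing of an LPS/zVAD array noisier than them, so the other probes of genes with more than 1 probe were compared as well, with a bootstrap 95% interval over genes. Overlaps of gene lists are printed with the number that independent lists would share.

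Gene lists were fixed before the data were examined. They numbered 32 and held 707 members, of which 632 were matched to a measured gene, 1 of them by an older symbol. The lists covered inflammatory mediators, the NF-kB pathway, interferon stimulated genes, type I interferons, AP-1 and MAPK immediate early genes, necroptosis and death receptors, the BCL-2 family and caspases, inflammasome and pyroptosis, the unfolded protein and integrated stress response, the NRF2 response, heat shock, cholesterol synthesis, LXR targets and lipid handling, hypoxia and glycolysis, cell cycle and DNA replication, macrophage identity, alternative activation, suppressors of cytokine signalling and tolerance, antigen presentation and costimulation, lysosome and cathepsins, p53 targets, AhR and tryptophan metabolism, housekeeping genes, ribosomal proteins and the mitochondrial genome, with markers of neutrophils, B cells, T and NK cells, dendritic cells, mast cells and basophils, stromal cells and erythroid cells. The mitochondrial genome list, with 0 measured members, and Ripk1, with no probe of a single symbol, were not analysed here. For each list and comparison the median log2 ratio of all measured members was placed among the medians of 10000 random lists of the same size, drawn from genes in the same 20 bins of mean signal. The percentile describes these arrays and is no p-value.

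Genes named in the text followed a rule fixed in advance. It took, for each comparison, the 10 highest and 10 lowest log2 ratios among filtered genes at least 2-fold apart (leaving out predicted, RIKEN and numbered clone symbols, olfactory and vomeronasal receptors, small RNAs and antigen receptor segments), up to 4 members of each list with the largest absolute ratio, and 20 key genes, of which 19 were measured. A gene named in 1 comparison may be followed in another. Where few members of a list passed the threshold, or a lost share is given for single genes, names outside the rule were chosen after their values were seen.

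Alternatives fixed in advance were thresholds of 1.5-fold and 3-fold, no filter and a filter at the 75th percentile, centring each array on its median, quantile normalization, cyclic loess, the mean of a gene's probes, all probes with or without a symbol, list medians over filtered members, means in place of medians, random lists not matched on signal, and a return of at least 2-fold in place of the midpoint. Leaving out a replicate and a pseudocount for linear values did not apply, as each condition has 1 array and the values are logarithmic. Raising signals under the filter level to it was chosen after seeing the data, and gives the bounds printed for folds against such signals.

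The computation was tested on simulated data for LPS/zVAD against LPS over 12203 genes, with error again from the spread of LPS/zVAD/Nec-1 against LPS. At the 2-fold threshold it recovered 2% of 50 genes simulated at 1.5-fold, 44% of 50 at 2-fold, 100% of 50 at 3-fold and 98% of 50 at 4-fold, and it called 89 of 12003 unchanged genes (0.74%). Of 400 lists with no shift, 5% lay in the lowest or highest 2.5% of random lists, and a list of 20 genes moved by a log2 ratio of 0.5 lay at percentile 100. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for cyclic loess.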

Results

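Gene expression was measured in bone-marrow-derived macrophages of female BALB/c mice, which are macrophages grown out of marrow in medium conditioned by L929 cells, a source of macrophage colony stimulating factor. The cells were left untreated (control), given lipopolysaccharide (LPS, a ligand of the receptor TLR4, 10 ng/ml), given LPS with zVAD (an inhibitor of caspases, 50 µM), or given LPS with zVAD and Nec-1 (necrostatin-1, an inhibitor of the kinase RIPK1, 30 µM). Each of the 4 conditions had 1 Affymetrix array, so no difference below has a replicate check, no p-value was computed, and no spread between replicates could be measured. The number of arrays limits the precision of every value. Treatment times are not given in the sources used here. The series holds no array of zVAD alone, Nec-1 alone or LPS with Nec-1, so effects of either inhibitor by itself cannot be separated. The 35556 probes had median log2 signals of 6.52 in control, 6.41 with LPS, 6.46 with LPS/zVAD and 6.49 with LPS/zVAD/Nec-1, and the highest signals lay between 14.5 and 14.6. The control array correlated least with the others, at a Pearson r over probes of 0.965 with LPS, 0.959 with LPS/zVAD and 0.968 with LPS/zVAD/Nec-1. Among the arrays with LPS, r was 0.984 between LPS and LPS/zVAD, 0.988 between LPS/zVAD and LPS/zVAD/Nec-1, and 0.992 between LPS and LPS/zVAD/Nec-1. Counts below are of the 12203 named genes past a filter on low signal, and "higher" or "lower" in a count means by at least 2-fold between single arrays.

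The LPS array was compared with the control array to describe the response to LPS itself. Cytokine, chemokine and interferon response genes had the highest ratios. A signal under the filter level (log2 6.47) was not separated from background here, so a fold against such a signal is given as a bound counted from that level. Il6, an inflammatory cytokine, was at least 84.8-fold higher with LPS (log2 4.58 in control and 12.88 with LPS), Il1a at least 180-fold and Ptgs2, the inducible cyclooxygenase, at least 119-fold. The chemokines Ccl5, Cxcl10 and Cxcl11, with control signals above the filter level, were 147-fold, 136-fold and 121-fold higher. The guanylate binding protein genes Gbp5 and Gbp2b, the interferon-inducible Ifi214 and AA467197 completed the 10 highest ratios as deposited, with bounds of 42.7-fold (Ifi214) to 87.0-fold (AA467197). The order of these 10 genes is not settled by such signals. At the other end, Rasgrp3, an exchange factor for Ras proteins, was at least 10.5-fold lower (log2 9.87 and 5.21). Plau, the urokinase plasminogen activator, had a log2 ratio of -3.32 and Rrm2, a subunit of ribonucleotide reductase, one of -2.93. Tmem273, St6gal1, Cdca7l, Gcnt1, Fbxo5, Gpr183 and Tcf19 were also among the 10 lowest, with log2 ratios from -3.43 (Tmem273) to -2.89 (Tcf19). In all, 1005 genes were higher and 879 lower with LPS than in control, and 629 were higher and 581 lower than control in each of the 3 arrays with LPS, which share that control array and are not replicates of one another.

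Among the fixed gene lists, the interferon stimulated genes stood highest in this comparison: all 38 measured members were higher with LPS, with a median log2 ratio of 3.91. Of 34 inflammatory cytokines, chemokines and mediators, 26 were higher and 0 lower (median 2.97), among them Nos2, the inducible nitric oxide synthase (log2 6.58 and 13.03), Il1b (7.83 and 13.77), Il12b, a subunit of interleukin 12 (5.94 and 12.17), and Tnf (10.75 and 12.57). Csf2 stood at log2 5.19 and 5.26, under the filter level. Of 21 genes of the NF-kB pathway and its feedback, 19 were higher and 0 lower (median 2.25), led by Traf1 and Nfkbiz with log2 ratios of 4.49 and 3.41, and with Tnfaip3 and Nfkbia, both negative regulators of the pathway, at 2.92 and 2.38. The list of cytokine signalling suppressors and tolerance had 15 of 18 members higher (median 2.18, Socs3 at 5.36 and Cd274, which encodes PD-L1, at 5.23), and antigen presentation and costimulation had 12 of 18 (median 1.47, Cd40 at 4.86 and Cd86 at 3.22). Of 17 inflammasome and pyroptosis genes, 8 were higher (median 0.93), including Casp4 at 3.54 and Casp1 at 2.80. Of 26 necroptosis and death receptor genes, 9 were higher and 0 lower (median 0.43). Zbp1, a nucleic acid sensor, had a log2 ratio of 3.94, Mlkl, the executor of necroptosis, 2.93, Casp8 0.67 and Ripk3 -0.40. The 38 immediate early genes of the AP-1 and MAPK list had 9 members higher and 2 lower (Dusp6 and Myc), with a median of 0.63. The medians of these 8 lists lay at percentiles 99.8 to 100 among 10000 random lists matched on mean signal.

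Proliferation and sterol synthesis genes stood at the opposite end. Of 39 cell cycle and DNA replication genes, 33 were lower and 0 higher with LPS (median log2 ratio -1.63, percentile 0), including the replication helicase genes Mcm7 at -2.65 and Mcm2 at -2.55 and the cyclin gene Ccne2 at -2.33. Of 20 cholesterol synthesis genes, 7 were lower and 0 higher (median -0.58, percentile 0.14), including the squalene epoxidase gene Sqle at -2.30 and the sterol carrier gene Stard4 at -2.17. Markers of other cell types differed among themselves. The neutrophil marker list had a median of 0.46, with 4 of 15 members higher (Lcn2 at 3.48, Mmp9 at 1.66, S100a9 at 1.12 and Ly6g at 1.03), and the dendritic cell list a median of 0.22, with 4 of 12 higher (Ccl17 at least 70.3-fold, counted from the filter level, Ccr7 at 3.88, Fscn1 at 2.43 and Itgax at 1.61). The stromal list had 4 of 16 members higher, Kdr at 2.84, Dcn at 2.82, Pecam1 at 1.77 and Cdh5 at 1.02, around a median of -0.14 that turned to 0.02 after cyclic loess and a mean of 0.43. Counted from the filter level, Dcn was at least 4.16-fold and Pecam1 at least 3.16-fold higher, and Cdh5 1.96-fold. Of 11 mast cell and basophil genes, Hdc was higher, at 3.50 (median -0.14, mean 0.20). B cell and T and NK cell markers had 0 of 11 and 0 of 15 members past the threshold, and their medians of -0.08 and -0.06 turned to 0.02 and 0.04 with centred arrays. Erythroid markers had 1 of 7 lower (Tfrc at -1.41), with a median of -0.12. Of the first 2 lists, 13 of the 15 neutrophil and 6 of the 12 dendritic cell genes were past the signal filter in these macrophages, and 1 and 3 members also belong to another list. Past the filter too were 12 of 16 stromal, 4 of 7 erythroid, 4 of 15 T and NK cell, 2 of 11 B cell and 2 of 11 mast cell and basophil genes. The medians of the last 3 lists therefore rest mostly on signals under it. Centring each array on its median moved the median log2 ratio of all genes from -0.12 to -0.01, and the counts then were 1130 higher and 698 lower.

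**Figure D1:**
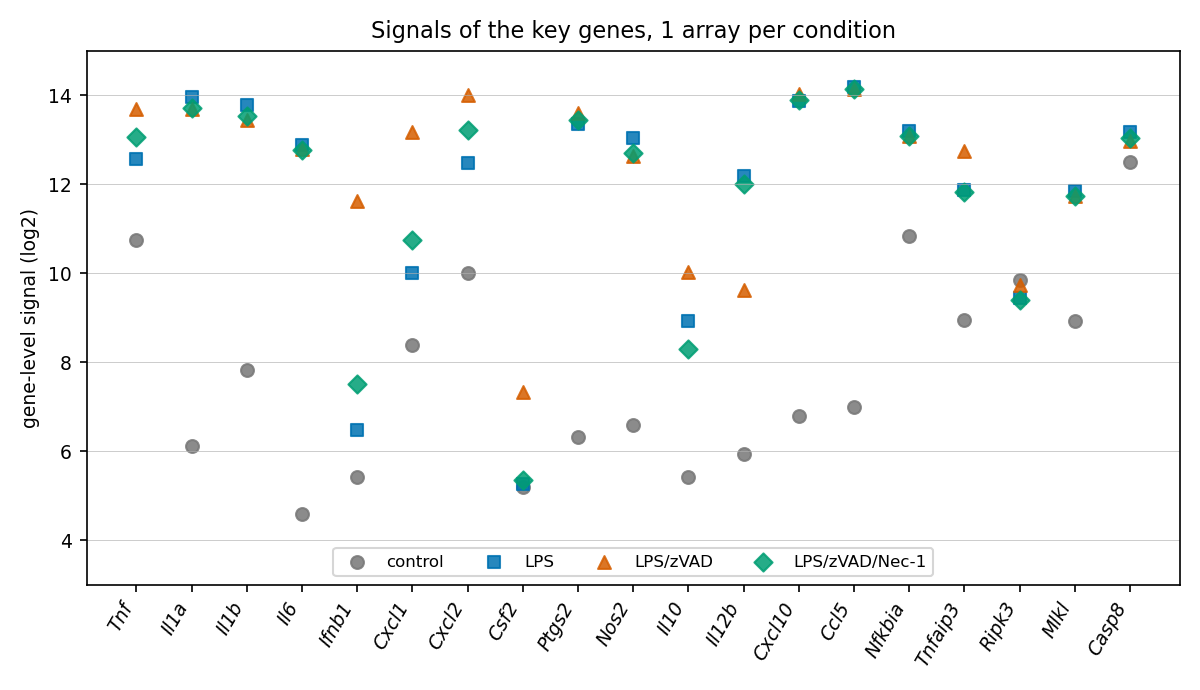
Log2 gene-level signal (y axis) of the 19 measured key genes (x axis), with 1 point per array: control (circle), LPS (square), LPS/zVAD (triangle) and LPS/zVAD/Nec-1 (diamond). There are no error bars because each condition has 1 array. Ifnb1 reached 11.62 with LPS/zVAD against 6.48 with LPS and 7.51 with LPS/zVAD/Nec-1, while Il12b was at 9.62, 12.17 and 12.00.

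The LPS/zVAD array was set against the LPS array to see what the caspase inhibitor added to the LPS response. Ifnb1, the gene of interferon beta, had the highest ratio, 35.3-fold higher with zVAD (log2 6.48 with LPS and 11.62 with LPS/zVAD). Next came Gem, a small GTP-binding protein (34.9-fold), the growth factor gene Bmp2 (at least 18.1-fold) and Lif, a cytokine of the interleukin 6 family (at least 13.1-fold). Prrg4, Gprc5a, Hamp, which encodes the iron hormone hepcidin, and Zbtb10 were higher by at least 18.2-fold, 12.4-fold, 13.3-fold and 6.05-fold. These bounds are counted from the filter level, since the LPS signals of the 6 genes from Bmp2 to Zbtb10 lay under it and that of Ifnb1 lay just above it, so their order is not settled. Plau, which was 10-fold lower with LPS than in control, was 12.8-fold higher with zVAD (log2 13.14, against 12.78 in control), and Osm, oncostatin M, was 11.6-fold higher. The lowest ratios were smaller. Cp, the copper-binding ferroxidase ceruloplasmin, was 6.7-fold lower (log2 12.33 and 9.59), and Il12b was 5.87-fold lower (12.17 and 9.62). Clec4a1, a C-type lectin receptor, Siglece, an inhibitory sialic acid receptor, Shisa3, Tmem176b, Tmem176a, Hp, which encodes haptoglobin, Il1f6, a cytokine of the interleukin 1 family, and Gpr18 had log2 ratios from -2.65 (Clec4a1) to -2.36 (Gpr18).

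Immediate early genes formed the list with the highest median. Of 38 AP-1 and MAPK immediate early genes, 15 were higher with zVAD and 1 lower (Dusp2), with a median log2 ratio of 0.64 (percentile 100). The transcription factor genes Maff and Egr1 had log2 ratios of 3.46 and 2.86, the growth factor Hbegf 3.44 and the kinase gene Plk2 2.76. Of 34 inflammatory cytokines, chemokines and mediators, 11 were higher, 4 lower and 19 under 2-fold (median 0.09, mean 0.45, percentile 98.3 among lists matched on signal and 88.2 among unmatched ones). Those higher included Lif, Osm, the neutrophil chemokines Cxcl1 (9.04-fold; log2 10.00 and 13.18) and Cxcl2 (2.88-fold; 12.48 and 14.01), Csf2, the gene of GM-CSF (log2 5.26 and 7.33, which is 1.82-fold when counted from the filter level), Tnf (2.18-fold; 12.57 and 13.70) and the anti-inflammatory cytokine Il10 (2.17-fold; 8.91 and 10.03). Those lower were Il12b, Ccl17, Ptges and Cxcl3. Several of the genes with the highest LPS responses had log2 ratios between -0.40 (Nos2) and 0.25 (Ptgs2) here. Il6 stood at 12.88 with LPS and 12.80 with LPS/zVAD, Il1a at 13.96 and 13.69, Il1b at 13.77 and 13.45, Nos2 at 13.03 and 12.63, Ptgs2 at 13.36 and 13.61, and Ccl5 at 14.19 and 14.14. These signals lie near the top of the array range, where a ratio can be compressed.

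Of the 10 measured type I interferon genes, Ifnb1 was the single one higher with zVAD (list median 0.26, percentile 99.9). Only 3 of the 10 passed the signal filter, so this median and percentile rest mostly on signals under it. Ifna2, next in size as deposited, was at log2 6.08 and 7.04, and its LPS signal lay under the filter level, so its rank is not settled. Of the 38 interferon stimulated genes, 1 was higher (the transcription factor Irf1, log2 11.46 and 12.81) and 0 were lower. Their median log2 ratio was 0.03 as deposited and turned to -0.01 when each array was centred on its median. It lay at percentile 98.1 among random lists matched on signal, and at 51.4 among unmatched ones. In the NF-kB list 1 of 21 members was higher (the kinase gene Map3k8) and 2 lower (Ikbke and Bcl3), with a median of -0.14 (percentile 42.0, and 1.94 among unmatched lists). Tnfaip3 was at log2 11.87 and 12.75 and Nfkbia at 13.20 and 13.08. Of the 26 necroptosis and death receptor genes, 2 were higher (the TLR adaptor gene Ticam1 and the deubiquitinase gene Otulin) and 0 lower. Ripk3, Mlkl and Casp8 had log2 ratios of 0.29, -0.13 and -0.19. In the inflammasome list 4 of 17 members were lower and 0 higher (median -0.44, percentile 0.27), namely the adaptor gene Pycard at -1.49, Mefv at -1.18, Nlrc4 at -1.09 and Naip5 (log2 9.27 and 8.27). Of 30 macrophage identity genes, 4 were lower and 0 higher (median -0.24, percentile 3.19, and 0.04 among unmatched lists): the chemokine receptor genes Ccr2 at -2.03 and Cx3cr1 at -1.66, the transcription factor gene Maf at -1.57 and Aif1 at -1.37. The neutrophil marker list lay lower too, with a median of -0.41 (percentile 0.82) and Mmp9, Lcn2 and Mmp8 lower by at least 2-fold, and the dendritic cell list had 2 members lower (Ccl17 and Fscn1), with a median of -0.02.

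In all, 396 genes were higher and 438 lower with LPS/zVAD than with LPS. The balance depended on the scaling of the arrays. Of these genes, 47.5% were in the higher direction as deposited and 42.1% with centred arrays (371 higher and 510 lower). The share was 57.8% after quantile normalization (433 higher and 316 lower) and 59.7% after cyclic loess (462 and 312). In simulated data with error from the spread of LPS/zVAD/Nec-1 against LPS, 44% of genes with a true 2-fold difference and 100% of those with a 3-fold difference passed the threshold. A true difference equal to the threshold falls on either side of it about equally often, whatever the error. The error of the LPS/zVAD array itself was not in these data, so the shares are no measure of sensitivity for this comparison.

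Nec-1 was added to LPS/zVAD to ask which differences depend on the kinase activity of RIPK1. Many of the genes with the highest zVAD ratios had the lowest ratios here, while Gem, Plau and Osm lay outside the 10 lowest, at log2 ratios of -2.82, -2.43 and -2.17. Ifnb1 was 17.3-fold lower with Nec-1 (log2 11.62 with LPS/zVAD and 7.51 with LPS/zVAD/Nec-1), Bmp2 16.9-fold, Lif at least 13.1-fold and Hamp 12.9-fold lower. Prrg4, F3, the gene of tissue factor, Tnn, Zbtb10, Il2 and Gprc5a completed the 10 lowest ratios as deposited. Tnn, Zbtb10 and Il2 lay under the filter level once Nec-1 was present, and counted from it they were at least 9.44-fold, 6.05-fold and 3.02-fold lower, so this order is not settled. The log2 ratios of Prrg4 and Gprc5a were -3.38 and -3.16. Il12b had the highest ratio, 5.22-fold higher with Nec-1 (log2 9.62 and 12.00), and Cp was 4.0-fold higher (9.59 and 11.60). Gpr31b, the fractalkine receptor gene Cx3cr1, Gpr18, Sephs2, Tor4a, the integrin gene Itgal, Tifab and Clec4a1 made up the rest of the 10 highest, with log2 ratios from 2.05 (Gpr31b) to 1.78 (Clec4a1). Over all genes, 139 were higher and 405 lower with Nec-1 than without it.

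The immediate early list stood apart here too, in the opposite direction to zVAD. Of the 38 immediate early genes, 15 were lower with Nec-1 and 0 higher (median log2 ratio -0.73, percentile 0), including Maff at -3.09, Hbegf at -2.40, the nuclear receptor gene Nr4a3 at -1.92 and Csrnp1 at -1.88. Of the 34 inflammatory genes, 8 were lower (Lif, Cxcl1, Osm, Csf2, Il10, Csf1, Edn1 and Tnfsf15, with Csf2 at 1.82-fold when counted from the filter level) and 1 higher (Il12b), with a median of -0.09 and a mean of -0.48 (percentile 0.82, and 0.12 among unmatched lists). Tnf was at log2 13.70 without and 13.07 with Nec-1, and Cxcl2 at 14.01 and 13.22, both under 2-fold. The list of cytokine signalling suppressors and tolerance had 3 members lower (Socs2 at -2.85, Cish at -2.06 and Il10 at -1.73) and 1 higher (Irak3 at 1.39), with a median of -0.19 (percentile 0.41). The interferon stimulated genes had 0 members higher and 0 lower (median -0.08, percentile 1.43). Of the inflammasome genes Pycard was higher, at 1.06 (list median 0.23, percentile 95.4), and of the macrophage identity genes Cx3cr1, Maf and Ccr2 were higher, at 1.92, 1.59 and 1.08 (list median 0.11, percentile 82.0). The neutrophil list had 0 members past the threshold (median 0.10).

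Gene by gene, most zVAD differences were smaller with Nec-1 present. Of the 396 genes higher with zVAD, 390 (98.5%, Wilson 95% interval 96.7 to 99.3%, which treats genes as independent draws) lay at or under the midpoint of the LPS and LPS/zVAD log2 signals once Nec-1 was present. Of the 438 genes lower with zVAD, 326 (74.4%, 70.1 to 78.3%) lay at or above it. The median gene lost 86.2% of its log2 difference in the higher group (quartiles 75.2 and 97.8%) and 67.3% in the lower group (49.3 and 81.2%). Ifnb1 lost 80.0%, Cxcl1 76.8% and Il12b 93.4%, whereas Tnf lost 56.3%, Cxcl2 52.1% and Gem 55.1%. Among the genes lower with zVAD, Hp lost 22.6% and Siglece 38.7%, and Abca1, a cholesterol exporter, kept its difference (log2 10.03 with LPS, 7.93 with LPS/zVAD and 7.92 with LPS/zVAD/Nec-1).

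The LPS/zVAD array enters both differences, so its own error returns some genes by chance. The simulated sets below gave all 3 arrays the error seen between the other 2, so they do not cover an LPS/zVAD array noisier than those. In 200 simulated sets with no effect, a median of 34 genes were higher with zVAD and 17 of them returned to the midpoint, with a highest count of 27, and for lower genes these values were 33, 16 and 27. In simulated sets that kept the observed zVAD differences but gave Nec-1 no effect, 5.25% of the higher genes and 5.68% of the lower genes returned. These sets took the measured LPS/zVAD signals as true, so the error of that array counted as an effect that Nec-1 left in place. They called medians of 488.5 higher and 601 lower genes, and their shares are low values for a return through error alone. Across genes, which are not independent replicates, the log2 ratios with zVAD and with Nec-1 had a Pearson r of -0.88, against a mean of -0.50 in the simulated sets with no effect. The covariance was -0.232 against -0.0344, a difference of -0.198. Of the 396 genes higher with zVAD, 306 were lower by at least 2-fold with Nec-1, where independent lists would share 13.1, and of the 438 lower with zVAD, 129 were higher by at least 2-fold, against 4.99. Part of both excesses may come from the shared array.

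**Figure D2:**
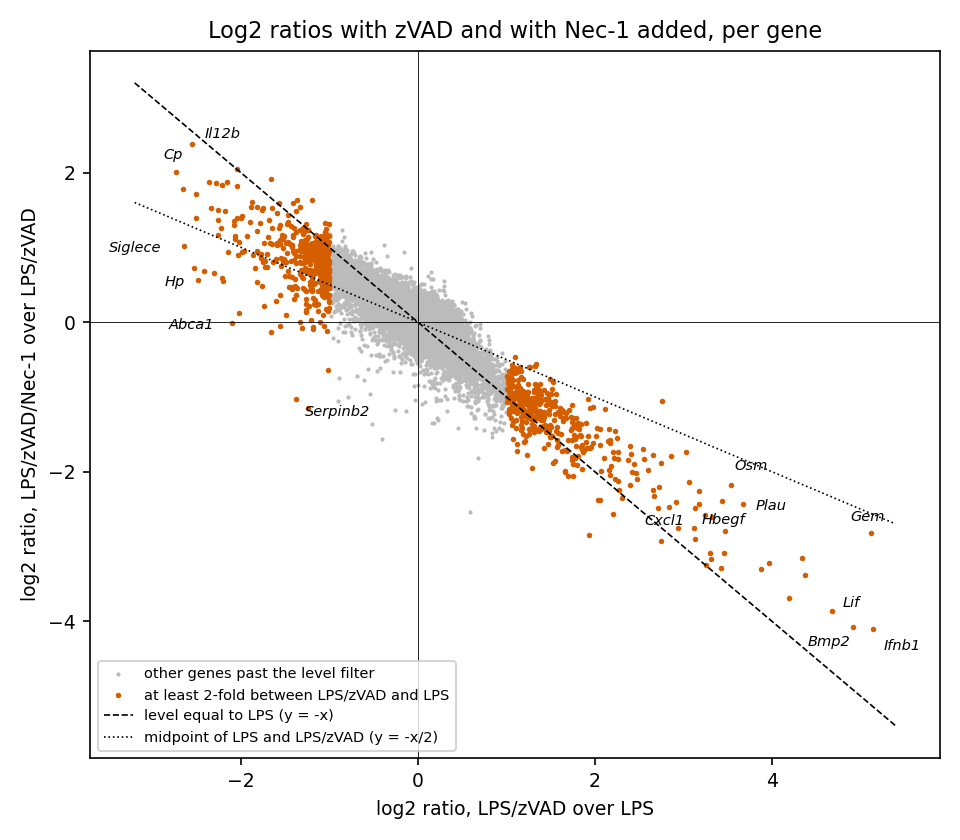
Log2 ratio of LPS/zVAD over LPS (x axis) against log2 ratio of LPS/zVAD/Nec-1 over LPS/zVAD (y axis) for 12203 genes (1 point each), with genes at least 2-fold apart between LPS/zVAD and LPS in orange. Points on the dashed line returned to the LPS level with Nec-1 and points on the dotted line to the midpoint, and the 2 ratios share the LPS/zVAD array. Of the orange genes on the right, 390 of 396 lie on or under the dotted line, and of those on the left, 326 of 438 lie on or above it.

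Finally, LPS/zVAD/Nec-1 was set against LPS to show what remained with both inhibitors present. Only 9 genes were higher (8 when signals under the filter level were raised to it, which left out Gprc5a). All 9 were also among the 396 higher with zVAD, where independent lists would share 0.29: Gem (4.9-fold; log2 7.82 with LPS and 10.13 with both inhibitors), the kinase gene Plk2 (3.26-fold), Osm (2.57-fold), the deubiquitinase gene Otud1, Plau, Gprc5a, Egr1, Hbegf and Ifnb1 (2.04-fold; 6.48 and 7.51). Of the 66 genes that were lower (58 with signals under the filter level raised to it), 41 were also lower by at least 2-fold with LPS/zVAD, where independent lists would share 2.37, and 51 belonged to the genes higher with LPS than in control, against 5.44. These overlaps share the LPS array, whose error adds to them. The lowest were Serpinb2, an inhibitor of plasminogen activators (5.3-fold lower; log2 9.55 with LPS, 8.18 with zVAD added and 7.16 with both inhibitors), Scd2, a fatty acid desaturase (10.01, 8.77 and 7.62), and Abca1. Zfp931, the interleukin 2 receptor chain gene Il2ra, Serpinb10, Hp, Rasgrp1, Slamf1 and Shisa3 (log2 ratio -1.80) completed the 10 lowest ratios as deposited. Zfp931 and Serpinb10 lay under the filter level with both inhibitors, and counted from it Serpinb10 was at least 3.28-fold lower and Zfp931 1.34-fold, which is under the threshold.

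Most key genes were close to their LPS level in this comparison. Il6, Il12b, Cxcl10, Ccl5, Ptgs2, Nfkbia, Tnfaip3, Ripk3, Mlkl and Casp8 had log2 ratios between -0.17 (Il12b) and 0.08 (Ptgs2), while Cxcl1 was at 0.74, Cxcl2 at 0.73, Tnf at 0.49 and Il10 at -0.61. Of the 34 inflammatory genes, 1 was higher (Osm) and 3 lower (Cxcl3, Ccl17 and Ptges), with a median of -0.01 that was 0.03 over the members past the signal filter. The 38 interferon stimulated genes had 0 members past the threshold, and their median of -0.0036 turned to 0.032 after quantile normalization. The immediate early genes had 3 members higher (Plk2, Egr1 and Hbegf) and 1 lower (Fosl2), with a median of 0.02 that turned to -0.05 when arrays were centred on their medians. Several lists lay apart from random ones with few or no members past the threshold. Above 0 were the cell cycle genes, with a median of 0.15 (percentile 100) and 29 of 39 members above 0 but 0 past 2-fold. The type I interferon genes had a median of 0.37 (percentile 100), with 8 of 10 members above 0 and Ifnb1 past 2-fold, but 3 of the 10 passed the signal filter. Others had medians under 0. The 28 hypoxia and glycolysis genes had a median of -0.32 (percentile 0) with Egln3 at -1.64 and Egln1 at -1.01, both oxygen-sensing prolyl hydroxylases. The suppressors of cytokine signalling had a median of -0.25 (percentile 0), the inflammasome genes -0.25 (percentile 0.02) and the NF-kB genes -0.22 (percentile 0), each with 0 members past 2-fold. The neutrophil markers had a median of -0.34 (percentile 0.01, Mmp9 and Mmp8 lower), NRF2 targets one of -0.13 (percentile 1.02) and alternative activation genes one of -0.08 (percentile 1.69, and 4.02 among unmatched lists, with Arg1 lower). Of the 15 alternative activation genes, 10 passed the signal filter. The dendritic cell markers had Ccl17, Itgax and Fscn1 lower, but their median of -0.03 lay within the middle 95% of random lists (percentile 5.10).

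**Figure D3:**
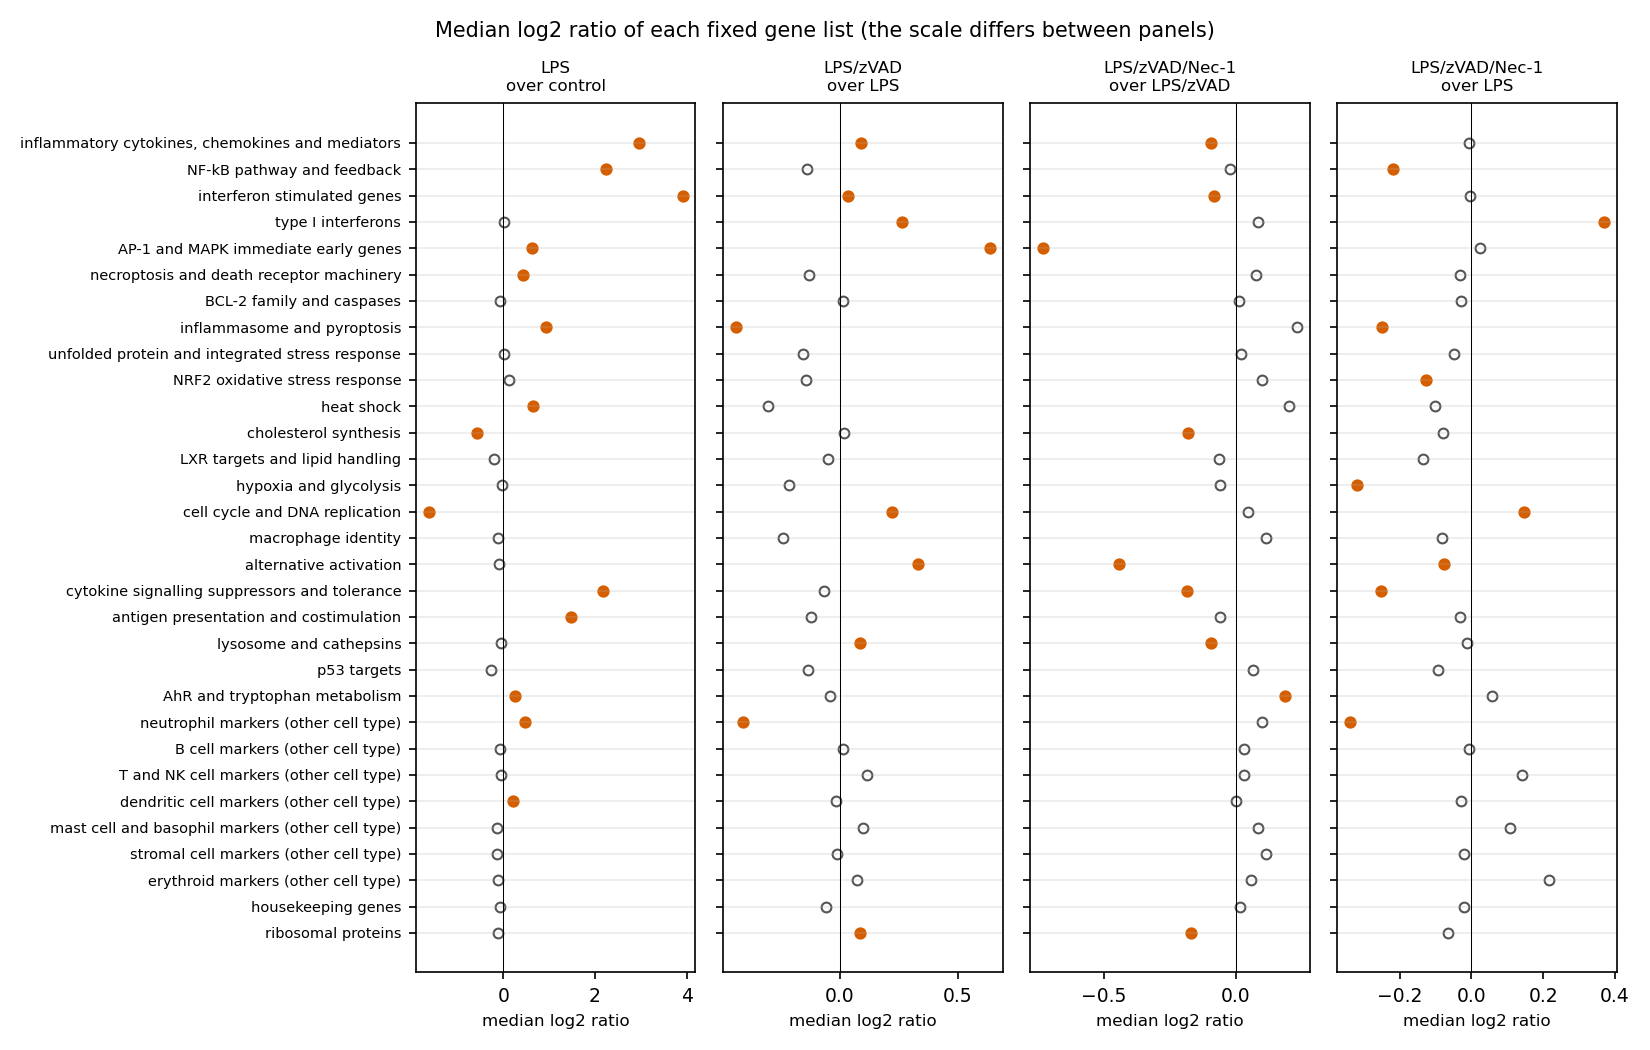
Median log2 ratio (x axis, with a different scale in each panel) of 31 fixed gene lists (y axis) in the 4 comparisons of single arrays. Filled points lie in the lowest or highest 2.5% of 10000 random lists of the same size matched on mean signal, and open points lie between. The immediate early genes stand at 0.64 with zVAD and at -0.73 with Nec-1 added, and the interferon stimulated genes, at 3.91 with LPS, stand at 0.03 with zVAD, a sign that turns to -0.01 when arrays are centred on their medians.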

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

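Each condition has 1 array, so no replicate could be left out and nothing here was tested; values that moved are given without a cause, since the cause was not tested, except that thresholds and filters change how many genes pass by construction. Every alternative below was fixed before the data were examined, except that raising signals under the filter level (log2 6.47) to it was chosen after seeing the data. No paired analysis was possible because each condition has 1 array. In all, 93 of 130 counts, shares and correlations, 553 of 744 list medians and 2393 of 2400 log2 ratios of named genes moved by less than the limits set for them (1.5 times for a count, its Wilson interval for a share, a bootstrap spread over genes for the correlation, the spread of random lists for a median, the spread of genes of like signal for a ratio). Of 124 list percentiles, 103 stayed on their side of the outer 2.5%, 15 moved into it and 6 out of it with unmatched lists. The 7 named-gene ratios that moved did so with the mean of a gene's probes, and 0 of them changed sign. All 600 named ratios stayed within their limit under each of the 3 scalings. That limit is the spread over many genes, and a mean of probes leaves a gene with 1 probe as it was. The tally of named genes is therefore a weak check of single ratios. For genes at or under the filter level the signal over background limits what a ratio can show. With such signals raised to that level, the 10 counts and 2 shares stayed within their limits and the correlation was -0.883.

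At 1.5-fold, higher and lower genes numbered 1752 and 2109 (LPS against control), 971 and 1607 (LPS/zVAD against LPS), 892 and 999 (Nec-1 added to LPS/zVAD), 90 and 336 (LPS/zVAD/Nec-1 against LPS), and 1069 and 1487 (all 3 LPS arrays against control). At 3-fold they numbered 545 and 269, 144 and 77, 16 and 109, 2 and 20, and 375 and 127 in the same order. In LPS/zVAD/Nec-1 against LPS, 43 genes were lower with the filter at the 75th percentile, and over every probe 64 were higher and 230 lower.

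The share of zVAD-higher genes that Nec-1 returned to the midpoint was 95.3% at 1.5-fold, 99.3% at 3-fold and 94.8% over every probe, and that of zVAD-lower genes 66.2% at 3-fold, 69.2% after cyclic loess and 63.2% over every probe. Asking for a return of at least 2-fold gave 77.3% and 29.5%. The correlation of the 2 ratios across genes was -0.84 with no filter, -0.92 with the stricter filter, -0.88 after quantile normalization (-0.882) and cyclic loess (-0.881), and -0.80 over every probe.

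For LPS against control, the inflammatory list median was 3.07 with centred arrays, 3.49 over filtered members and 3.34 as a mean, the interferon stimulated mean was 4.27, and the immediate early median 0.73 with centred arrays. For LPS/zVAD against LPS, the means were 0.45 (inflammatory) and 0.93 (immediate early), and the interferon stimulated median was -0.01 (-0.0112) with centred arrays, the opposite sign, and 0.10 (0.104) after cyclic loess. The inflammatory and interferon stimulated medians lay at percentiles 88.2 and 51.4 of random lists not matched on signal, against 98.3 and 98.1 of matched ones. With Nec-1 added to LPS/zVAD, the means were -0.48 (inflammatory) and -0.85 (immediate early), and the mean of the AhR and tryptophan metabolism list was -0.020, opposite in sign to its median of 0.19. In that list 5 of 13 members passed the signal filter. For LPS/zVAD/Nec-1 against LPS, the inflammatory median was -0.083 with centred arrays and 0.028 over filtered members. The interferon stimulated median there was -0.078 with centred arrays, 0.032 after quantile normalization and 0.056 after cyclic loess, and the immediate early median -0.050, 0.083 and 0.087 in the same order, with a mean of 0.084.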

Other observations

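Some lipid and stress genes also differed with zVAD. Of 18 LXR targets and lipid handling genes, 5 were at least 2-fold lower in LPS/zVAD than in LPS (Abca1, Mylip, Nr1h3, Scd2 and Abcg1) and 3 higher, the fatty acid binding protein genes Fabp4 and Fabp5 and the nuclear receptor gene Pparg. Fabp4 was at log2 9.42 with LPS, 11.69 with LPS/zVAD and 9.45 with LPS/zVAD/Nec-1, and Pparg had log2 ratios of 2.01 with zVAD and -1.53 with Nec-1 added. Of the 5 lower genes, Abcg1, Nr1h3 and Mylip lost 78.9%, 72.9% and 70.1% of their log2 difference with Nec-1 added. Abca1 did not return, and Scd2 was lower still. The list median of -0.05 turned to 0.01 after quantile normalization. Of 27 unfolded protein and integrated stress response genes, 3 were higher with zVAD (Ppp1r15a at 3.24, Chac1 at 1.49 and Atf4 at 1.16) and 0 lower, while the list median was -0.16 and its mean 0.16, of opposite sign. Ppp1r15a, a phosphatase subunit that reverses translational arrest, was at 8.65, 11.89 and 9.32 in the same 3 arrays. Insig1, a sterol sensor, was the single cholesterol synthesis gene of 20 higher with zVAD, at 2.23, around a list median of 0.02 that turned to -0.03 with centred arrays, and the list median with Nec-1 added was -0.18 (percentile 1.04). The feedback inhibitors of cytokine receptors Socs2 and Cish had log2 ratios of 1.94 and 1.75 with zVAD, and Irak3, an inhibitor of TLR signalling, had -2.04. Their list of 18 suppressors had 3 members higher (with Il10) and 2 lower (with Lcn2). Its median of -0.07 (percentile 55.5) turned to 0.005 after cyclic loess, and its mean was 0.10. The alternative activation list had a median of 0.33 with zVAD (2 of 15 higher, the transcription factor genes Egr2 and Klf4) and -0.44 with Nec-1 added (percentile 0). Of its 15 members, 10 passed the signal filter. Egr2 and Klf4 also belong to the immediate early list and were counted there.

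Further lists of LPS/zVAD against LPS are given with percentiles among random lists matched on signal. Cell cycle genes had a median of 0.22 (percentile 100; Mcm4 and Cdc20 higher), lysosome genes 0.09 (percentile 99.2, and 84.2 among unmatched lists; Atp6v0d2 higher) and ribosomal proteins 0.09 (percentile 98.9, and 81.7 among unmatched lists). Ribosomal proteins had -0.17 once Nec-1 was added, where all 23 members lay under 0. Within the middle 95% of matched lists lay hypoxia and glycolysis genes at -0.22 (percentile 7.60; 4 of 28 lower, Ndrg1 higher), heat shock genes at -0.31 (8.66; Hsph1 and Chordc1 lower) and NRF2 targets at -0.15 (22.7; Gsr lower). These 3 lay at percentiles 0.06, 0.41 and 1.63 of unmatched lists. The p53 targets, at -0.14 (percentile 27.3; Sesn1 lower), and antigen presentation genes, at -0.12 with a mean of 0.02 (43.7; Cd83 and Cd86 higher), lay in the middle 95% of both. The medians of BCL-2 family and caspase genes (0.01, turning to -0.03 with centred arrays), AhR and tryptophan genes (-0.04, with a mean of 0.01) and housekeeping genes (-0.06, with a mean of 0.03) had no settled sign. Among markers of other cell types, T and NK cell genes had a median of 0.12 (Il7r higher), mast cell and basophil genes 0.10 with a mean of -0.05 (Hdc lower), erythroid genes 0.07, turning to -0.01 after cyclic loess, B cell genes 0.01, turning to -0.03 with centred arrays, and stromal genes -0.01 (Dcn and Pecam1 lower). Most T and NK cell, B cell, mast cell and basophil, and AhR and tryptophan genes lay under the signal filter.

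Of the tests in the next 3 paragraphs, those of the shared LPS/zVAD array, of a level trend, of the single LPS/zVAD culture and of genes lower with LPS were chosen only after the result was seen. The genes higher with zVAD came back with Nec-1. Each probe here is a gene-level entry, so error of single probes inside an entry was not seen. Error of single entries on the LPS/zVAD array is argued against by the other entries of 26 of these genes. Their median log2 ratio with zVAD was 0.87 (bootstrap 95% interval 0.587 to 1.12), against -0.01 for the other entries of 815 genes. The rest of the 396 had no other distinct entry, and a probe sequence shared between transcripts was not examined. A level trend of that array is argued against for the genes higher with zVAD. They numbered 462 after cyclic loess removed such trends, more than the 396 as deposited. Those lower with zVAD went from 438 to 312, so this argument does not extend to them. A difference of that single culture that has nothing to do with zVAD cannot be told apart from an effect of zVAD, since the series has 1 LPS/zVAD array, and under it the Nec-1 array would return in the same way. The series also has no array of LPS with Nec-1, so an action of Nec-1 on the LPS response itself, or apart from RIPK1, cannot be separated. Cell survival was not measured here, so a difference in it between the cultures cannot be told apart either. A RIPK1 kinase dependent response to caspase inhibition, the question of the series, therefore stays a candidate explanation among those left open.

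Ifnb1 was 35.3-fold higher with zVAD, yet the interferon stimulated genes stayed at about their LPS level. They may have been near the top of the array range already, since 35 of 38 had log2 signals above 11.36 with LPS, and of the 1237 genes above that level 11 were at least 2-fold higher with zVAD. Yet that level lies well under the highest LPS signal of 14.6, and room was left above it. Irf1 rose from 11.46 to 12.81. Cxcl2 and Tnf, with LPS signals above that of Stat2 (12.46), had log2 ratios of 1.53 and 1.13. Between Irf1 and Stat2 in LPS signal, Xaf1, Mx2 and Oas1a had ratios of 0.28, 0.71 and 0.11. Oas3, Bst2, Iigp1, Zbp1 and Stat2 had -0.41, -0.56, -0.06, -0.12 and -0.33. For the members up to Stat2 these values argue against compression on the array. Of the 38 members, 20 were above and 18 below their LPS signal with zVAD. The members below the level, Cxcl9, Oas2 and Eif2ak2, had a median log2 ratio of -0.16 with zVAD (-0.344 to 0.247), under the 0.5 set in advance as the least that a hidden response would show. That bound assumed more members under the level. By themselves 3 genes, each already at least 2-fold higher with LPS, are too few to exclude compression for the other 35. For members with LPS signals above that of Stat2 it stays open. Whether the interferon response was at its limit in the cells, or had too little time to follow Ifnb1, was not decided by these values. Nor was a limit on the array for the members above Stat2.

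Genes lower with zVAD were often those that LPS had made higher: 176 of 438 (40.2%), where independent lists would share 36.1 genes, and 73 of 396 (18.4%, against 32.6 genes) among those higher with zVAD. Both comparisons use the LPS array, whose error raises the first share; by LPS/zVAD/Nec-1 against control, which avoids it, that share was 25.8% (Wilson 95% interval 21.9 to 30.1%) against 6.85% of all genes, which argues against that error as the whole cause. The second share was then 24.5% (20.5 to 29.0%), and with LPS signals away from both ends of the range the order turned, at 24.3% (20.1 to 28.9%) and 27.6% (22.8 to 33.0%), but that array keeps part of the zVAD differences, which draws the shares together, so larger variation in either direction cannot be told apart from a lower response for genes that LPS had made higher. For genes that LPS had made lower, equal variation is argued against, as they were 5.71% (3.90 to 8.29%) of the zVAD-lower and 14.4% (11.3 to 18.2%) of the zVAD-higher genes, and 6.27% and 13.8% away from both ends. A smaller response to LPS with zVAD may underlie this for 57 of those genes, the zVAD-higher ones, out of 937 in all. For genes that LPS had made higher these values cannot decide.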
